A study of Mus musculus with 14 samples.

How the data were processed

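Single-cell libraries were 10x Chromium 3' libraries, made with v2 kits except the second irradiated library, which used a v3 kit per the labels. Their matrices hold UMI counts per gene and barcode. Per the submitters' processing notes these counts came from Cell Ranger with builds mm10 and GRCm38, and the notes of the second adult and second irradiated libraries name version 3.0.1 together with cutadapt, STAR, HTSeq and DESeq2. Per the file headers the software version was 3.0.0 in 6 matrices, and 2 headers gave none. The bulk libraries were Smart-seq2 libraries, and per the submitters' processing notes their reads were handled with cutadapt, STAR, HTSeq and DESeq2 on mm10, with no versions. The deposited bulk table holds a normalised signal, gene read counts divided by 1 size factor per library: every library's values were whole multiples of 1 step (100% within a tolerance of 0.01), which gave 7356280 to 11916314 recovered reads per library against deposited totals of 9212600 to 10191000, and Actb took 4.1% to 5.99% of them. Coordinates come from GENCODE M21, which uses the same build, GRCm38. The bulk table gives symbols and the single-cell matrices identifiers with symbols. Reads shared by near-identical copies (Bglap and Bglap2, Hspa1a and Hspa1b, the haemoglobin pairs) make those genes uncertain. The counting is not stated to use strand.

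The bulk table had 17823 lines with 17626 symbols, of which 197 lines repeated a symbol and 180 of these held identical values. Since the table did not hold counts, log2(value + 1) was tested with limma 3.58.1 (trend, robust) in R 4.3.3, with genes kept where at least 3 libraries had a value of at least 1, leaving 14450 genes, and with Benjamini-Hochberg adjustment at 0.05. The samples correlated at 0.981 to 0.983 within BMSCs alone, 0.976 to 0.98 within co-culture and 0.968 to 0.979 between groups, and chi-square per degree of freedom within groups was 6.00 to 17.6, so no library repeated another. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The recovered reads were also tested with edgeR 4.0.16 and DESeq2 1.42.0, chosen after seeing the data. On simulated reads of 14267 genes for this comparison, limma recovered 26.9% of genes changed 1.5-fold, 76.1% changed 2-fold and 98.5% changed 4-fold, with 17 false calls.

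Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. In each library the cells with the top scrublet scores (scanpy 1.11.5) were removed as doublets at a rate of 0.8% per 1000 barcodes, because scrublet's own threshold marked 0.0855% to 0.757%. Barcodes numbered 3346 and 1972 in the adults, 2744 in the aged, 2764 in the rosiglitazone, 1057 in the first irradiated, 2811 in the fracture and 4680 in the Prrx1-Cre library, and 16496 cells were kept in all. Seurat 5.3.0 normalised them, took 2000 variable genes and 30 principal components, integrated libraries by RPCA and found 18 clusters at resolution 0.8. A cluster was named after the fixed marker list with the highest score, if the score was at least 0.5, at least 3 markers were detected at a CPM of 10, over 50% of the list's markers were 1.5-fold higher than in other clusters, and its 10 leading genes held no more markers of another list. The marker share, leaving tied clusters unnamed, the merging of periosteal fibroblast and tenocyte lists, and the class used as background for each gene were set after the clusters were seen. So was the comparison set for leading genes. Against all other clusters, the 10 leading genes of CAR clusters 0 and 10 each held 1 marker of another class (Ibsp and Car3) and none of their own. Those of cluster 10 began with Fabp4 and included Cd36. Against clusters of other classes all 8 CAR clusters passed. Results without these 2 clusters and by cluster are therefore given too. Among the CAR clusters, 3 was led by immediate-early and 9 by interferon genes.

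UMIs were summed per library over the CAR class and given as CPM. With 1 library per condition there was no test: a gene was counted when it was at least 2-fold above the higher or below the lower adult, with a CPM of at least 50 on the higher side, and 4103 genes reached that floor in some library. Ratios are to the nearer adult, with exact 95% Poisson intervals in scipy 1.17.1, and a count of 0 was set to a floor of 3 counts per library. A list's median log2 ratio, of CPM + 5 against the mean of the adults' log2 values and over members with a mean CPM of at least 5, was placed among 10000 random lists of its size matched on expression in 20 bins. For the 5 libraries compared, simulated counts gave back 76.1% to 91.0% of genes changed 3-fold and all changed 6-fold, and 6 to 21 other genes were called. Clusters entered the comparison by cluster with at least 50 cells in the condition and in both adults, which left 0, 1, 2 and 5. Shares of cells carry exact Clopper-Pearson 95% intervals.

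The 20 gene lists, 19 marker lists, tests and the rule for named genes were fixed before the data were examined. In bulk that rule took the 12 highest and 12 lowest log2 differences among called genes whose groups did not overlap and whose higher mean was at least 10, and up to 4 members of each list. In each condition it took the 10 highest and 10 lowest ratios and up to 4 members of each list. Lepr, Cxcl12 and Kitl are given in every condition. The planned edgeR test of 2 irradiated against 2 adult libraries was not run, because the matrix of the second irradiated library has 17762 lines and its gene file 17778, so that its values cannot be tied to genes, and the rule for single libraries was applied to the first irradiated library instead. Alternatives were other pseudocounts, filters, scalings, clusterings and fold rules, leaving out each library, and a block for replicate number. All columns of the bulk table were mapped to samples.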

Results

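Skeletal stromal cells of C57BL/6 mice were profiled in 14 samples that formed 8 groups. Single-cell libraries numbered 8, and 7 of them held Lepr-Cre traced cells sorted from bone marrow and bone fragments as CD45-, Ter119- and Tie2-negative, a gate against blood, erythroid and endothelial cells. The Cre reporter stays on in descendants, so osteoblasts and other progeny of Lepr+ cells, the perivascular stroma of the marrow, keep the label. The Lepr-Cre groups were adults of 8 weeks (2 libraries), mice of 12 months (1), mice of 10 weeks fed rosiglitazone, an agonist of the adipogenic receptor PPARγ, from week 5 (1), mice given 5 Gy of irradiation at week 7 and taken 1 week later (2), and mice taken 1 week after a femur fracture made at week 7 (1). The eighth library held Prrx1-Cre traced cells, the progeny of limb mesenchyme, from mice of 8 weeks, with the same negative gates and with Col2.3-GFP+ osteoblasts gated out. The 6 bulk libraries came from Pdgfra+ bone marrow stromal cells (BMSCs) held for 5 days in a 3D hydrogel, alone (3) or with bone marrow endothelial cells (3). Cells kept per single-cell library numbered 2837 and 1783 in the adults, 2218 in the aged, 2476 in the rosiglitazone, 750 in the first irradiated, 2298 in the fracture and 4134 in the Prrx1-Cre library. Median UMIs per kept cell were 2948 and 2434 in the adults, 1962 in the aged, 2094 in the rosiglitazone, 1657 in the irradiated, 4016 in the fracture and 4004 in the Prrx1-Cre library. Total UMIs ran from 1642418 in the first irradiated to 22304015 in the Prrx1-Cre library, and bulk libraries held 7356280 to 11916314 recovered reads. The second irradiated library is not compared here. The labels do not say that samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

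The co-culture asked how endothelial cells alter the transcriptome of marrow stromal cells. Genes of mural cells, the pericytes and smooth muscle that wrap vessels, rose: Rgs5, a pericyte regulator of G-protein signalling, went from a normalised read count of 12.1 ± 6.47 alone to 190.3 ± 39.0 with endothelial cells (SD, n = 3 each; log2 difference 3.97, SE 0.31). The potassium channel gene Kcnj8 went from 7.47 ± 3.24 to 97.5 ± 9.30 (log2 difference 3.62), smooth muscle actin Acta2 from 186 ± 18.8 to 577 ± 58.5 (1.62), the myosin light chain gene Myl9 from 992 ± 66.3 to 1963 ± 34.1 (0.99) and the adhesion gene Mcam from 4.42 ± 3.74 to 22.95 ± 11.3. Heyl, a Notch target, was listed at 0 in all 3 libraries of BMSCs alone and at 10.1, 24.2 and 15.7 in co-culture. The guanylate cyclase gene Gucy1a1 rose from 1.25 ± 2.16 to 18.2 ± 6.02, the endothelial sialomucin gene Emcn from 2.58 ± 1.45 to 25.3 ± 3.61, the adipokine gene Serpina12 from 32.5 ± 0.199 to 124 ± 9.74, and the acute-phase gene Saa3 from 8870 ± 1310 to 21810 ± 3590. Kitl, the stem cell factor that sustains haematopoietic stem cells, fell from 1950 ± 138 to 1253 ± 142 (log2 difference −0.64, SE 0.12), osteopontin (Spp1) from 120300 ± 21600 to 70510 ± 8470, and the transcription factor gene Mef2c from 66.4 ± 9.13 to 23.3 ± 6.00 (log2 difference −1.50, SE 0.25). The zinc-finger gene Zfp292 fell from 67.8 ± 7.82 to 23.04 ± 5.13. In each of these genes all 3 libraries of one group lay above all 3 of the other, which the rule for the highest and lowest genes required. Of all 14450 genes 3732 (25.8%) were separated in this way, against 10% for a random order of libraries. Cxcl12, the chemokine that retains blood progenitors in marrow, Lepr and Adipoq did not pass, at 51960 ± 9460 and 63660 ± 4790, 261.5 ± 18.1 and 263.4 ± 42.9, and 38350 ± 2160 and 39480 ± 4960 in BMSCs alone and in co-culture (limma adjusted p 0.167, 0.997 and 0.885). On GRCm38, Rgs5 lies on chromosome 1 from 169655501 to 169695813, Kcnj8 on chromosome 6 from 142564837 to 142571614, Acta2 on chromosome 19 from 34241090 to 34255590, Emcn on chromosome 3 from 137341067 to 137432185, and Kitl on chromosome 10 from 100015630 to 100100416, each a protein-coding gene. Across 14450 genes, limma called 494 at an adjusted p under 0.05 (146 higher, 348 lower, Benjamini-Hochberg), with adjusted p of 1.56e-05 for Rgs5, 5.41e-06 for Kcnj8 and Acta2, 1e-04 for Myl9, 0.000544 for Heyl, 0.00161 for Emcn, 4.56e-05 for Saa3, 0.00704 for Kitl, 0.00593 for Spp1 and 0.00415 for Mef2c. Log2 differences are of normalised count + 1 and understate the change of low genes. The balance of directions depended on single libraries: the count was 62 (40 higher, 22 lower) without replicate 1 of BMSCs alone, 88 (43 and 45) without its replicate 3, 901 (385 and 516) without its replicate 2 and 256 (69 and 187) without replicate 2 of co-culture. Without replicate 1 of BMSCs alone, limma's adjusted p was 0.068 for Kitl, 0.0637 for Spp1, 0.0534 for Mef2c and 0.18 for Mcam. Without its replicate 3 it was 0.0519 for Spp1 and 0.0966 for Mcam, and without replicate 2 of co-culture 0.11 for Mcam. The other genes called here passed in every fit without 1 library in which they were tested.

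**Figure D1:**
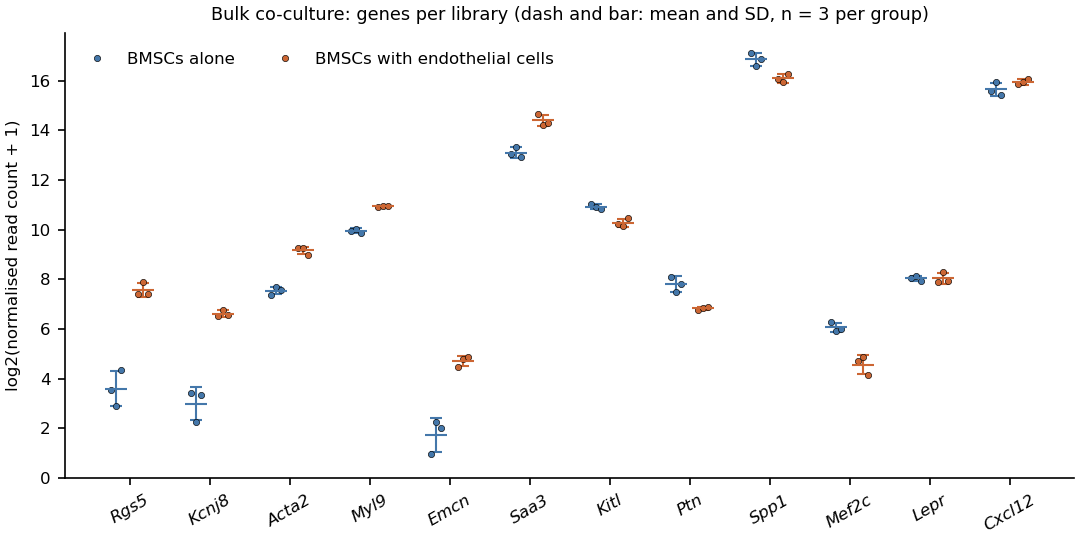
Log2(normalised read count + 1) of 12 genes in each of the 3 libraries of BMSCs alone and the 3 with endothelial cells, with points for libraries and a dash and bar for the mean and SD of the log values. Mean normalised counts of Rgs5 were 12.1 alone and 190.3 in co-culture, and those of Kitl 1950 and 1253.

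Of the 38 gene lists tested in the co-culture, 6 passed camera, a test of each list against all other genes, at a preset correlation between genes, and none at an estimated correlation. Of 9 measured mural markers, 5 rose (Rgs5, Kcnj8, Mcam, Acta2 and Myl9) and 4 did not pass, with 7 higher when adjusted over the list alone. Notch3, a mural receptor of the Notch pathway, was at 100.3 ± 17 alone and 166 ± 39.4 in co-culture (SD, n = 3; limma adjusted p 0.0584). Among 12 immediate-early and dissociation-stress genes 4 rose, 5 when adjusted over the list alone. They were Ier2 (4664 ± 316 to 6743 ± 310), Junb (8978 ± 1370 to 12650 ± 689), Hspa1a (134.7 ± 24.9 to 222.5 ± 33.7) and Dnajb1 (2358 ± 208 to 3134 ± 170), growth-response and heat-shock genes. Of 11 interferon-response genes 1 fell, 5 when adjusted over the list alone, and Ifit1, an antiviral effector, went from 122 ± 58.5 to 33.3 ± 13.4 (limma adjusted p 0.043). Lists of 12 periosteal and Sca-1 fibroblast genes and of 10 periosteal fibroblast markers each held 1 gene that fell, the matrix proteoglycan gene Ogn (1260 ± 53.4 to 863 ± 166), and no gene that rose over all genes tested, while 7 and 6 were higher when adjusted over the list alone. Of 7 monocyte and macrophage markers none passed, and the abundant Lyz2 was at 624 ± 269 and 1218 ± 506 (n = 3; limma adjusted p 0.388). Camera gave these 6 lists an adjusted p of 4.86e-11 for mural genes, 0.0216 for immediate-early genes and 0.0232 for each of the others, upward except for the interferon list. At the estimated correlation camera's adjusted p was 0.0682 for mural genes, 0.462 for both periosteal lists and 0.576 for the other 3. The mural list passed camera without any 1 library (highest adjusted p 4.32e-08). The immediate-early list was at 0.0911 without replicate 3 of BMSCs alone and 0.0511 without replicate 2 of co-culture. The interferon list was at 0.212 without replicate 2 of BMSCs alone, and at 0.0518 and 0.144 without replicates 1 and 2 of co-culture. Both periosteal lists were at 0.0613 without replicate 2 of BMSCs alone and 0.13 without replicate 3 of co-culture. The macrophage list was at 0.0757 and 0.0911 without replicates 1 and 3 of BMSCs alone, and at 0.0602 and 0.13 without replicates 1 and 3 of co-culture. Single genes also lost their call: limma's adjusted p without replicate 3 of BMSCs alone was 0.094 for Ier2, 0.14 for Junb, 0.185 for Hspa1a, 0.205 for Dnajb1 and 0.0986 for Ogn, and without its replicate 1 it was 0.21, 0.1, 0.1, 0.141 and 0.0715 for Junb, Hspa1a, Dnajb1, Ogn and Ifit1. Without replicate 2 of BMSCs alone it was 0.0715 for Dnajb1 and 0.0952 for Ifit1. Without replicate 1 of co-culture it was 0.0977 for Hspa1a, 0.111 for Dnajb1, 0.0836 for Ogn and 0.108 for Ifit1, without its replicate 2 it was 0.073, 0.102, 0.0635, 0.0869 and 0.109 for Junb, Hspa1a, Dnajb1, Ogn and Ifit1, and without its replicate 3 it was 0.104 for Dnajb1.

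Several lists of stromal function did not pass camera in co-culture. Niche factors, the cytokines that support blood progenitors, held 2 genes that fell of 10 measured, Kitl and Ptn (226.8 ± 48.1 to 113.8 ± 4.84, SD, n = 3), and 3 when adjusted over the list alone (camera adjusted p 0.288). Osteoblast genes held 3 that fell of 17, among them Spp1 and the collagenase gene Mmp13 (1036 ± 153 to 647 ± 140), and the same number adjusted over the list alone (0.0654). Chondrocyte markers held 2 that fell of 8 (3 over the list alone, 0.0575), Notch genes 1 that rose of 10, Heyl (3 higher and 2 lower over the list alone, 0.276), and acute-inflammation genes 2 that rose of 12, Saa3 and the iron-binding lipocalin Lcn2 (3 over the list alone, 0.191). Of 5 measured endothelial markers only Emcn rose (0.276). Among markers too low to be tested, Pecam1 averaged 1.32 alone and 0.699 in co-culture, Cldn5 0.631 and 4.49 (0 to 10.2 in single co-cultures), Kdr 0 and 0.848, and Cdh5 0 and 0.761. Adipocyte identity, proliferation, hypoxia, cholesterol, angiogenic, BMP and Wnt lists held no passing gene, though over the list alone BMP and TGFβ targets held 3 higher and 1 lower and cholesterol genes 1 of each. Without replicate 1 of BMSCs alone limma's adjusted p was 0.0661 for Ptn and 0.108 for Lcn2. Without its replicate 3 it was 0.0519, 0.123 and 0.0923 for Ptn, Mmp13 and Lcn2, and without replicate 1 of co-culture 0.0581 for Mmp13. The labels do not say whether endothelial cells were removed before RNA was taken.

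The single-cell libraries asked which stromal classes the tracing reached at steady state and under stress. Lepr+ CXCL12-abundant reticular (CAR)-like cells, the main source of marrow niche factors, made up 80.5% (exact 95% binomial interval 79.0–82.0) and 82.5% (80.7–84.2) of kept cells in the adults and 88.9% (87.5–90.1) in the aged, 86.95% (85.6–88.3) in the rosiglitazone and 89.1% (86.6–91.2) in the first irradiated library. The fracture library held 40.4% (38.4–42.5) CAR-like cells, below both adults. In it fibroblast- or tenocyte-like cells, marked by Ly6a, Cd34 or Tnmd, were 23.1% (21.4–24.9) against 0.282% and 1.40% in the adults. Osteoblast-like cells were 8.09% (7.01–9.29) against 2.08% (1.59–2.68) and 1.12% (0.687–1.73), and chondrocyte-like cells 5.135% (4.27–6.12) against 0.0705% and 0.168%. The Prrx1-Cre library held 62.0% CAR-like (60.5–63.5), 5.49% fibroblast- or tenocyte-like (4.82–6.23), 4.69% chondrocyte-like (4.07–5.38) and 2.54% mural-like cells (2.08–3.07), the last against 0.388% and 0.729% in the adults. No chondrocyte-like cell was found among 2218 aged, 2476 rosiglitazone and 750 irradiated cells, which allows up to 0.135%, 0.121% and 0.4% on a limit of 3 cells. Osteo-primed cells, marked by Wif1, Limch1 and Alpl, were 15.2% and 13.7% in the adults, 9.56% in the aged, 12.2% in the rosiglitazone, 6.93% in the irradiated, 17.45% in the fracture and 17.9% in the Prrx1-Cre library. These shares depended on the clustering: at resolution 1.2 they were 6.13% and 6.62% in the adults and 2.16%, 3.15%, 2.93%, 9.84% and 10.1% in the other libraries in that order. Without integration they were 7.58% and 4.88% in the adults, 13.9% in the irradiated library, then above both adults, and 46.3% in fracture. Unnamed cells were 5.09% of the fracture and 2.81% of the Prrx1-Cre library and at most 0.933% of the others. No test was made, since each condition had 1 library and no replicate check, and binomial and Poisson intervals here and below cover counting error only. The Col2.3-GFP gate sets the osteoblast-like share of the Prrx1-Cre library (2.06%), and Lepr, 1 of the 10 CAR markers, was itself lower in fracture cells. Without integration across libraries CAR-like cells were 11.1% of fracture cells, the fibroblast- or tenocyte-like share 32.5%, and no fracture cell was in a chondrocyte-like cluster. Clustered that way, 88.7% of the second adult library fell in the class named neutrophil lineage and 2.86% (51 cells) in the CAR class. The larger cluster of that neutrophil class, with 1595 cells, scored 0.872 for neutrophil and 0.77 for CAR markers. Against all other clusters its leading genes, Xist, Igfbp5 and Pi15 first, held no neutrophil marker, so its cells may be CAR-like. Chondrocyte-like cells were 0.696% of the fracture and 2.44% of the Prrx1-Cre library at a coarser resolution, and 2.84% of the fracture library with doublets kept.

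**Figure D2:**
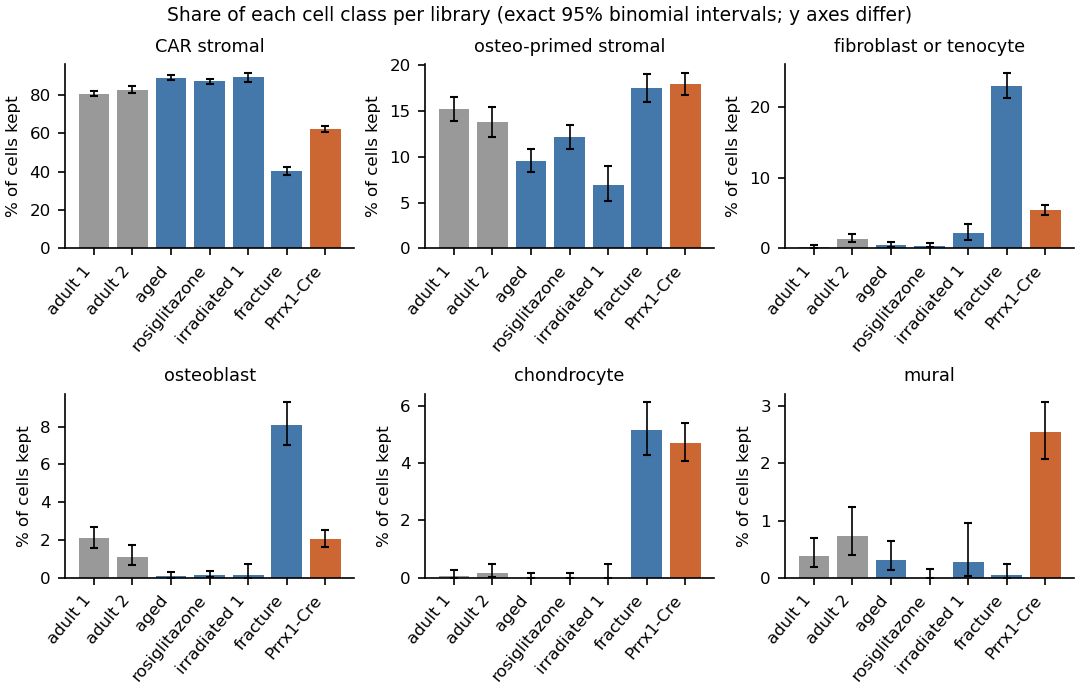
Percent of kept cells in 6 stromal classes for each of 7 single-cell libraries, as bars from 0 with exact 95% binomial intervals and with a separate vertical scale in each panel. Grey bars are the 2 adult libraries, blue the 4 conditions and orange Prrx1-Cre, and the CAR-like share was 40.4% in fracture against 80.5% and 82.5% in the adults.

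Shares of cells with a UMI were compared with every cell thinned to 2000 UMIs, which left out 689 and 640 adult, 1135 aged, 1156 rosiglitazone, 470 irradiated, 454 fracture and 499 Prrx1-Cre cells. Lepr was seen in 74.4% and 79.6% of adult cells (82.2% and 89.6% unthinned), 17.1% of fracture cells (15.4–18.9, 28.6% unthinned) and 48.0% of Prrx1-Cre cells (46.4–49.7, 63.8% unthinned), against 5.56% of chondrocyte-like cells (16.4% unthinned), which should lack it. Within the CAR class it was seen in 81.5% and 85.5% of adult cells, 37.9% of fracture cells (33.8–42.1, 47.4% unthinned) and 64.4% of Prrx1-Cre cells (78.4% unthinned). Ly6a, which encodes the progenitor antigen Sca-1, was seen in 0.885% and 2.01% of adult cells (1.13% and 1.96% unthinned), 10.5% of fracture cells (15.8% unthinned) and 8.47% of Prrx1-Cre cells (12.8% unthinned), against 1.43% of osteoblast-like cells (4.49% unthinned). Acan, the cartilage proteoglycan, was seen in 16.5% of fracture cells (22.2% unthinned) and 8.34% of Prrx1-Cre cells (12.4% unthinned), against 0.0931% and 0.350% of adult cells (0.141% and 0.280% unthinned) and 2.42% of mural-like cells (5.76% unthinned). Notch3 was seen in 20.0% and 26.9% of adult cells (28.3% and 34.0% unthinned), 10.7% of irradiated cells (13.6% unthinned) and 8.19% of fracture cells (15.1% unthinned), against 0.857% of osteoblast-like cells (5.62% unthinned). Bglap, the osteoblast hormone osteocalcin, was seen in 51.4% and 16.97% of adult cells (63.7% and 20.3% unthinned). It was seen in 2.31% of aged (2.48% unthinned), 3.86% of rosiglitazone (3.88% unthinned) and 16.1% of mural-like cells (33.1% unthinned). All but the first adult, the fracture (31.3%) and the Prrx1-Cre library (26.2%) lay near or below that mural-like level. Background classes here were pooled over libraries, so they do not give each library's own background. Of 139 mural-like cells 105 came from the Prrx1-Cre and 1 from the fracture library. In the first adult itself 11 mural-like cells held 1.27 Bglap UMIs per cell and CAR-like cells 1.02. Mki67, a cycling marker, was seen in 0.885% and 0.875% of adult and 1.36% of fracture cells (3.31% unthinned), against 0.286% of osteoblast-like cells (1.12% unthinned). Median UMIs of the cells compared were 3504 and 3143 in the adults, 4876 in fracture and 4301 in Prrx1-Cre cells, and 8830, 4535 and 9984 in the chondrocyte-, mural- and osteoblast-like cells used as background.

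Gene levels within the CAR class were compared as CPM of summed UMIs, from 1242075 UMIs of 668 irradiated cells to 9308643 UMIs of 2564 Prrx1-Cre cells, and genes at least 2-fold beyond both adults were counted. The 2 adult libraries themselves differed at least 2-fold at 353 genes over a CPM of 50 (99 higher and 254 lower in the first). Their contents differed too: haemoglobin genes took 11.7% of UMIs in the first adult, 10.8% in the Prrx1-Cre library and 0.254% in the second adult. Neutrophil markers such as S100a8 were lower in the first adult by a median log2 of −3.18, and immediate-early genes such as Fos were 2.15 higher. Lists differed between the adults as well: the first stood above the second by a median log2 of 1.26 for acute-inflammation, 0.63 for interferon and 0.55 for BMP and TGFβ genes (each at percentile 100 of random lists), and Lepr-identity genes were at −0.49 (percentile 2.23). Set against the other adult and a condition in the same way, the first adult lay beyond both at 22 to 87 genes and the second at 140 to 260. With the rosiglitazone library these were 87 and 140, and with the fracture library 64 and 202. The 65 and 63 genes counted below for those libraries lay under both. The counts of the aged, irradiated and Prrx1-Cre libraries lay between their own values. Scaling by TMM, a trimmed mean of log ratios, moved libraries by up to 0.21 log2.

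Aged CAR-like cells asked what 12 months of life change in the class. Snhg11 stood at 68.0 CPM (60.1–76.5) against 1.04 and 2.62 in the adults, 25.9 times the nearer adult (exact 95% Poisson interval 13.9–54.7). Single genes of the matrix were above both adults: Vtn, vitronectin, at 98.0 CPM was 8.12-fold higher (5.97–11.3), the proteoglycan Dcn at 1799 CPM was 4.82-fold higher (4.55–5.10) and its relative Lum 3.39-fold, while Efemp1, an elastic-fibre protein, was 4.26-fold higher. The fixed list of fibrous-matrix genes did not follow, with a median log2 ratio of −0.23, 0 of 14 above and 1, Tnc, below both adults. Cebpb, an adipogenic and acute-phase transcription factor, was at 2337 CPM against 565 and 635, or 3.68-fold (3.52–3.85). Of 17 osteoblast genes 2 lay below both adults, Bglap at 4.50 CPM against 346 and 68.4 (0.0657 of the nearer adult) and Col1a1, the main bone collagen, at 174 against 427 and 414 (0.420), and the list's median log2 ratio was −0.58, at percentile 0.03 of random lists with 3 members above 0. Markers of the osteo-primed class moved with it, at a median of −0.78 (percentile 0.07, 0 of 6 above 0 and none beyond both adults). The adult level of Col1a1 was near that of other cells, with 515 and 700 CPM in mural-like cells (11 and 13) and 313 in 11 neutrophil-lineage cells of the first adult. Bglap was at 314 CPM in the mural-like and 144 in the neutrophil-lineage cells of the first adult. The matrix glycoprotein Tnc was at 0.383 of the nearer adult and the Wnt ligand gene Wnt4 at 0.310. Cholesterol-synthesis genes had a median log2 ratio of 0.64 (percentile 100) and Notch genes −0.57 (percentile 0.74), with no member of either beyond both adults. The cholesterol median was not particular to the aged library. It was also at percentile 100 in the rosiglitazone (0.47) and irradiated (0.55) libraries, each with 1 member beyond both adults. Against the first and second adult alone the medians were 0.94 and 0.32 for cholesterol, −0.51 and −0.82 for Notch, −0.67 and −0.62 for osteoblast and −0.08 and −0.71 for fibrous-matrix genes. Lepr at 1229 CPM lay between the adults, and Cxcl12 at 23720 and Kitl at 928 were 0.869 and 0.822 of the nearer adult. In all, 92 genes were beyond both adults (37 higher and 55 lower, or 40.2% higher against 52.5% after TMM scaling), 274 against the first adult alone (109 and 165) and 544 against the second (137 and 407). Lower genes included 4 haemoglobin genes at 0.164 to 0.205 of the nearer adult, and erythroid and neutrophil markers had medians of −3.05 (−3.76 and −2.26 against each adult) and −2.30 (−0.70 and −3.89). Immediate-early and dissociation-stress genes had a median of 0.93 (percentile 100), which turned with the adult used (−0.32 and 1.86). Bglap shares nearly all its sequence with Bglap2, so its count is uncertain. All 26 genes named for this library lay on the same side of both adults in each of the 4 clusters with enough cells. The genes were picked from the sum that holds these same cells, so this is not independent support. With the CAR class defined without integration, few cells of the second adult were left in it. The ratio was then 40.7 for Snhg11, 4.25 for Vtn, 0.233 for Bglap and 0.584 for Tnc. Snhg11 lies on chromosome 2 from 158375638 to 158386145, and the annotation used lists it as protein-coding.

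Rosiglitazone asked how PPARγ activation changes CAR-like cells. Lipid-handling genes stood above both adults: the fatty-acid transporter Cd36 at 137 CPM (127–148.5) against 1.94 and 4.46 (30.8-fold, 19.1–53.3), the fatty-acid binding protein Fabp4 at 2219 against 71.4 and 107 (20.7-fold, 18.7–22.9), and the glycerol channel Aqp7 at 143 (8.02-fold, 6.24–10.45). The lipoprotein lipase Lpl at 8719 CPM was 2.91-fold higher (2.85–2.97), the adipokine Adipoq at 8046 was 2.10-fold higher (2.06–2.14), and the adhesion molecule Vcam1 at 5000 was 2.13-fold higher. Of 10 measured PPARγ targets 3 were beyond both adults (Cd36, Fabp4 and Aqp7) and 9 had a ratio above 0 on the log2 scale, with a median of 0.89 (percentile 100), and adipocyte-identity genes had a median of 0.72 (percentile 100, 3 of 9 beyond). Against the first and second adult alone these medians were 0.46 and 0.90, and 0.81 and 0.73. Osteoblast genes had a median of −0.75 (percentile 0, −0.82 and −0.75 against each adult), with 2 of 17 below both adults: Bglap at 12.6 CPM, 0.183 of the nearer adult (0.136–0.244), and Col1a1 at 163, 0.394 of it (0.361–0.430). Osteo-primed markers had a median of −0.58 (percentile 0.05, 0 of 6 above 0 and none beyond). The signalling modulator Rcan2 was at 0.212 of the nearer adult, Tnc at 0.341 and the glucocorticoid-induced Fkbp5 at 0.345. These falls were not particular to rosiglitazone. Fkbp5 was also below both adults in the aged, irradiated and fracture libraries, Rcan2 in the irradiated and fracture libraries, and Tnc in the aged library. By the same rule Bglap was below both in the aged library, and Col1a1 in the aged and irradiated libraries. In the first adult, Bglap was at 346 CPM in CAR-like, 314 in 11 mural-like and 144 in 11 neutrophil-lineage cells. Col1a1 was at 427, 515 and 313 CPM there, so free RNA from osteoblasts may set the adult levels of both genes. Lepr at 1601 CPM was 1.05, Cxcl12 at 25120 was 0.920 and Kitl at 1084 was 0.961 of the nearer adult. In all, 65 genes were beyond both adults (42 higher and 23 lower), 230 against the first adult alone (125 and 105) and 287 against the second, where most were lower (97 and 190). Haemoglobin genes were at 0.0734 to 0.143 of the nearer adult, and erythroid and neutrophil markers had medians of −3.53 (−4.27 and −2.74 against each adult) and −3.04 (−1.3 and −4.73). The immediate-early and dissociation-stress median of 0.48 (percentile 100) turned with the adult used (−0.83 and 1.59). All 25 genes named for this library lay on the same side in each of the 4 clusters, which hold cells from which the genes were picked. These mice were 10 weeks old and the adults 8. Where the class was defined without integration, with 51 cells of the second adult in it, the ratio to the higher adult was 1.32 for Cd36, 1.02 for Fabp4, 4.06 for Aqp7, 1.68 for Adipoq and 1.63 for Vcam1, and that to the lower adult 0.357 for Bglap and 0.582 for Tnc. Without clusters 0 and 10 the ratio to the higher adult was 71.0 for Cd36 and 45.1 for Fabp4. Both genes are among the leading genes of cluster 10, so this choice of cells depends on them. Fabp4 lies on chromosome 3 from 10204088 to 10208576 and Cd36 on chromosome 5 from 17781690 to 17888801.

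Irradiated CAR-like cells, taken 1 week after 5 Gy, showed lipid genes and p53 targets above both adults in the first irradiated library. Cd36 stood at 107 CPM (24.0-fold, 14.45–42.5) and Fabp4 at 1445 (13.5-fold, 12.1–15.04), the carbonic anhydrase Car3 at 989.5 against 35.2 and 16.5 (28.1-fold, 24.45–32.5), and Pparg itself at 163 against 76.8 and 64.2 (2.12-fold). PPARγ targets had a median log2 ratio of 1.17 (percentile 100), 3 of 10 beyond both adults (Cd36, Fabp4 and Aqp7) and all 10 above 0. Of 13 p53-response genes 5 were beyond both adults and all 13 above 0, with a median of 1.19 (percentile 100). Against the first and second adult alone the medians were 1.43 and 1.31 for PPARγ targets and 1.13 and 1.09 for p53 genes. The cell-cycle regulator Ccng1 was at 78.1 CPM (63.3–95.3) against 23.9 in both adults (3.27-fold, 2.43–4.41), Phlda3 at 375 (2.99-fold, 2.66–3.35), the nuclease Aen at 62.0 (2.42-fold) and the pro-apoptotic Bax at 386 (2.22-fold, 1.99–2.47). The last of the 5, the p53 inhibitor Mdm2, was 2.06-fold higher and was named after its value was seen. The chemokine gene Cxcl13 was above too, at 109.5 CPM against 6.11 and 6.29 (17.4-fold, 11.2–28.1), as were Ccl5, 10.7-fold, and 2 of 12 interferon genes, Irf7 at 2.29-fold and Ifit1 at 2.04-fold (1.95 after TMM scaling, 1.01 without integration), with a list median of 0.76 (percentile 100). That median was 0.31 against the first adult and 1.2 against the second, which differed from each other by 0.63. Below both adults were Heyl at 10.5 CPM against 76.0 and 247 (0.138, 0.0728–0.238), complement C3 at 22.5 against 155 and 321 (0.145), the angiopoietin-like Angptl1 (0.0874), Col1a1 (0.307) and bone sialoprotein Ibsp at 3777 against 13500 and 10950 (0.345). Acute-inflammation genes had a median of −0.89 (percentile 0) but a mean of −0.24 and medians of −0.33 against either adult alone, with 2 of 9 below both, C3 and the interleukin receptor Il1r1 (0.437, or 0.646 without integration). Lepr at 1254 CPM lay between the adults, and Cxcl12 was 0.943, Kitl 0.805 and Notch3 0.644 of the nearer. In all, 132 genes were beyond both adults (82 higher and 50 lower), 285 against the first adult alone (154 and 131) and 560 against the second, where most were lower (201 and 359). Haemoglobin genes were at 0.0052 to 0.00926 of the nearer adult, with an erythroid median of −6.18 (−6.95 and −5.41 against each adult). The neutrophil median of −1.13 turned with the adult used, at 0.56 against the first and −2.55 against the second. The immediate-early and dissociation-stress median of 0.96 (percentile 100) turned too, at −0.21 against the first and 2.51 against the second. The largest cluster of this class was 2 here (28.3%) and 0 in the adults (32.1% and 37.6%). Of 33 named genes 32 lay on the same side in each of 4 clusters, and the exception, Bnip3, had 0 UMIs in 1 of them, too few to place it. These clusters hold cells from which the genes were picked, so the agreement is not independent support. Defined without integration, the class gave a ratio to the higher adult of 0.909 for Cd36 and 0.497 for Fabp4, which then lay between the adults, 2.39 for Car3, 4.94 for Cxcl13, 1.70 for Pparg and 1.52 for Aen, and a ratio to the lower adult of 0.508 for Ibsp. Few cells of the second adult were left in the class under that setting, so these ratios rest on a small part of it. Without clusters 0 and 10 Cd36 was 44.5-fold and Fabp4 23.5-fold higher, and Pparg 1.91-fold. Cd36 and Fabp4 are among the leading genes of cluster 10, so this choice of cells depends on them. Ccng1 lies on chromosome 11 from 40748552 to 40755311.

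Fracture CAR-like cells, taken 1 week after injury, showed single matrix genes above both adults. Postn, the periosteal matricellular protein periostin, was at 83.2 CPM (72.4–95.2) against 1.49 and 4.72 (17.6-fold, 10.9–30.3), the repair collagen regulator Cthrc1 at 85.2 against 9.39 and 2.36 (9.07-fold, 6.82–12.2), and fibronectin Fn1 at 93.1 against 7.30 and 17.3 (5.38-fold, 4.08–7.18). Col1a1 stood at 903 against 427 and 414 (2.11-fold, 2.00–2.23), and at 856 CPM in the 11 erythroid cells of this library, which held 31 UMIs of it, 6 of Fn1 (166 CPM), 2 of Postn (55.2) and 1 of Cthrc1 (27.6). Its fibroblast- or tenocyte-like cells held Postn at 2833 CPM. The fibrous-matrix list had a median log2 ratio of −0.02 (percentile 36.4) with 2 of 15, Postn and Fn1, beyond both adults and 7 above 0, while 3 measured tenocyte markers had a median of 1.96 (percentile 100, none beyond). Osteo-primed markers had a median of 0.783 (percentile 100, 6 of 6 above 0 and none beyond, 0.715 and 0.995 against each adult). Periosteal and Sca-1 fibroblast genes had a median of 0.632 (percentile 100, 5 of 8 above 0 and 1 beyond, 1.08 and 0.262 against each adult). The imprinted genes Mest, at 52.9 CPM (14.4-fold, 8.29–27.1), and Meg3, at 106 (6.01-fold), and Comp, a cartilage and tendon matrix protein (3.50-fold), were above as well. Lepr lay below both adults, at 267 CPM (248–288) against 948 and 1531 (0.282, 0.260–0.305), as did C3 (0.358), Rcan2 (0.270) and Ibsp (0.497, or 0.552 after TMM scaling). Cxcl12 at 22980 CPM was 0.841, Kitl at 650 was 0.576 and Adipoq at 4213 was 1.10 of the nearer adult. Chondrocyte genes had a median log2 ratio of 1.37 (percentile 100, 7 of 7 above 0 and 1, Comp, beyond), BMP and TGFβ targets 0.55 (percentile 100, the same as between the adults), with Id1 and Id3, transcriptional inhibitors induced by BMP, 2.19- and 2.01-fold higher, and Lepr-identity genes −0.24 (percentile 0.26, with Lepr below), less than the −0.49 between the adults. Against the first and second adult alone the medians were 1.53 and 1.21 for chondrocyte, 0.37 and 0.66 for BMP and TGFβ, −0.19 and −0.48 for Lepr-identity and 0.46 and −0.23 for fibrous-matrix genes. In all, 63 genes were beyond both adults (25 higher and 38 lower, or 39.7% higher against 53.4% after TMM scaling), 186 against the first adult alone (81 and 105) and 428 against the second (103 and 325), and 486 when all stromal classes were summed. Haemoglobin genes were at 0.126 to 0.301 of the nearer adult, erythroid and neutrophil medians were −2.73 (−3.44 and −2.01 against each adult) and −2.27 (−0.47 and −4.09), and this library also held 118 chondrocyte-like cells. Of 25 named genes 24 lay on the same side in each of 4 clusters, which hold cells from which the genes were picked, and the exception was Mia. With the class defined without integration, few cells of the second adult were left in it. The ratio to the higher adult was then 1.53 for Mest, 1.89 for Meg3, 0.813 for Comp, 1.39 for Col1a1, 1.87 for Id1 and 1.81 for Id3, and that to the lower adult 0.661 for C3. Without the 2 clusters led by genes of other classes the first ratio was 1.59 for Id1, 1.71 for Id3 and 13.1 for Meg3. Without clusters 3 and 9, led by immediate-early and interferon genes, it was 3.03 for Meg3, 11.6 for Postn and 9.48 for Mest. Postn lies on chromosome 3 from 54361109 to 54391037 and Lepr on chromosome 4 from 101717404 to 101815352.

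Prrx1-Cre CAR-like cells asked whether the class looks alike under the broader mesenchymal label. Cartilage genes stood above both adults: Col2a1, the main cartilage collagen, at 207 CPM (198–217) against 1.49 and 3.15 (65.8-fold, 37.6–128), Col9a3 at 78.7 (88.1-fold, 40.3–241), Chad at 66.7 (149-fold, 50.8–725.5) and Lect1, the cartilage angiogenesis inhibitor, at 56.9 against 0 UMIs in either adult, at least 72.4-fold higher on a floor of 3 UMIs per library. Of 10 measured chondrocyte genes 3 were beyond both adults (Col2a1, Col9a2 and Comp) and 9 above 0 on the log2 scale, with a median of 2.24 (percentile 100). The library also held 194 chondrocyte-like cells, and Col2a1 was at 191 CPM in its mural-like and 104 CPM in its erythroid cells. Spp1 at 5231 CPM was 2.18-fold and Fabp4 at 256 was 2.39-fold higher (2.15–2.66). The cytokine-signalling inhibitor Socs2 stood at 24.9 CPM against 153 and 187 (0.163, 0.140–0.188), Rbpj, the transcription factor of Notch signalling, at 56.3 against 134 and 138 (0.419, 0.376–0.467) and the phosphate regulator Phex at 0.404 of the nearer adult. Lepr at 563 CPM was 0.594 and Kitl at 650 was 0.576 of the nearer adult, while Cxcl12 at 28640 and Adipoq at 3935 were 1.01 and 1.03 of it. Lepr-identity genes had a median of −0.38 (percentile 0.11; −0.24 and −0.56 against each adult) with no member beyond both adults, against −0.49 between the adults. Immediate-early and dissociation-stress genes had a median of 1.33 (percentile 100, 12 of 12 above 0), at 0.23 against the first and 2.26 against the second adult. Erythroid markers were at 0.73 (percentile 100; 0.14 and 1.36), and neutrophil markers at −0.65 (percentile 0.07), which turned with the adult used (1.25 and −2.6). In all, 41 genes were beyond both adults (19 higher and 22 lower, or 46.3% higher against 67.6% after TMM scaling), 99 against the first adult alone (28 and 71) and 513 against the second (98 and 415), and 120 when all stromal classes were summed. The balance also turned with the fold rule, at 22.4% higher at 1.5-fold and 83.3% at 3-fold. All 21 genes named for this library lay on the same side in each of the 4 clusters, which hold cells from which the genes were picked. Defined without integration, the class gave a ratio to the higher adult of 133 for Col2a1, 84.2 for Chad, 0.768 for Comp and 0.114 for Fabp4, and to the lower adult of 1.53 for Rbpj and 0.257 for Socs2. It then held few cells of the second adult. With doublets kept, Col2a1 was 40.97-fold and Chad 87.6-fold higher. Col2a1 lies on chromosome 15 from 97975602 to 98004695.

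**Figure D3:**
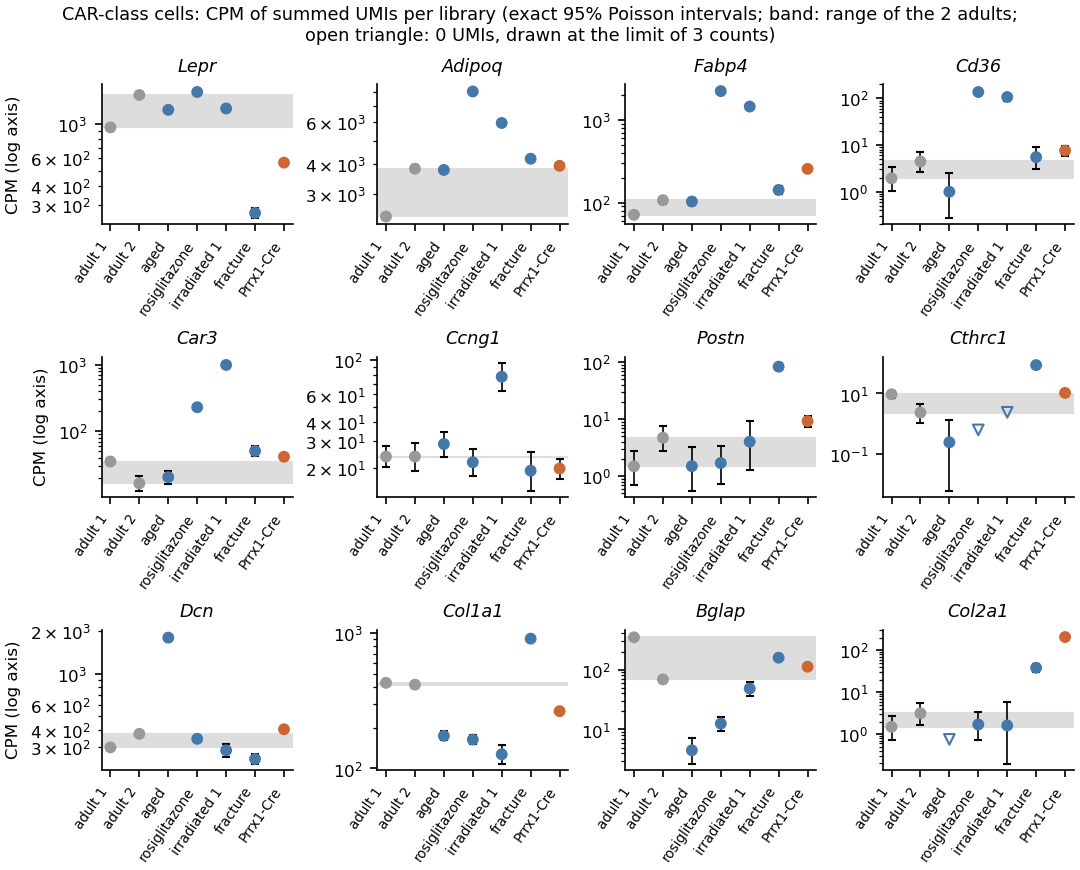
CPM on a log axis of 12 genes in CAR-like cells of 7 single-cell libraries, as points with exact 95% Poisson intervals, with a band for the range of the 2 adults and an open triangle at the limit of 3 counts where no UMI was seen. Lepr was at 267 CPM in fracture against 948 and 1531 in the adults, and Fabp4 at 2219 with rosiglitazone against 71.4 and 107.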

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

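The second irradiated library entered no comparison, and its depth stood above that of the adults. It held a median of 7130 UMIs and 2639 genes per barcode, against 2944 and 2338 UMIs and 1386 and 1301 genes in the adult libraries, from 3567 barcodes and 36242281 UMIs. It was made with a v3 kit and the adults with v2 kits, so chemistry and treatment differ together, and no explanation was tested. Ordering its genes by identifier gave a best Spearman correlation of 0.214 between its gene totals and those of the first adult over 17 offsets, against 0.938 for the first irradiated library.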

How the results depend on the processing

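The edgeR and DESeq2 fits on recovered reads, the fold rule for the irradiated library, the osteo-primed class, thinned sums and sums without haemoglobin genes, stress-led clusters or clusters 0 and 10, and single CAR or osteo-primed clusters were chosen after the data were seen. Under the alternatives run, none of the 44 called genes named in co-culture changed sign. For the 7 named genes not called, signs were not compared in fits where they stayed uncalled. In the conditions no gene was shown to move to the other side of both adults, though some came to lie between them and Bnip3 had 0 UMIs in 1 cluster of the irradiated library. In co-culture the count of 494 genes was 405 with a pseudocount of 0.1, 586 without a filter, 510 with edgeR on recovered reads (461 shared), 472 with edgeR on median-ratio factors and 531 with DESeq2 (427 shared), and 3 for changes beyond 2-fold. Leaving out 1 library gave 62 to 901 genes and 3 to 7 lists. With an estimated correlation 0 lists passed camera (3 at an unadjusted p under 0.05, against 10 in camera). Of the 6 lists, 3 also passed fry (the mural and both periosteal lists) and 3 did not (interferon, 0.253, immediate-early, 0.192, and macrophage, 0.287), while fry passed 3 others: fibrous-matrix, Notch and acute-inflammation genes. With the replicate number as a block 801 genes passed (272 higher, 529 lower), and 7 lists, since osteoblast genes then passed camera (adjusted p 0.0424), while limma's adjusted p was 0.0577 for Ifit1 and 0.0298 for Notch3, a call lost and a call gained. Same-numbered libraries had deviation correlations of 0.0253, 0.056 and 0.0486, all small, yet each library correlated best with its own number. Pairing by number is therefore neither shown nor excluded. Over 51 genes named in co-culture, 7 of them not called, the verdict was the same in 209 of 300 comparisons when a library was left out and in 282 of 337 under other settings, while 88 and 52 calls were lost, and 11 of 44 called genes kept the call in every fit without 1 library in which they were tested. The planned filter alternative equals the filter used. The irradiation test with 2 libraries per arm, its gene lists and its alternatives were not run.

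Counts of genes beyond both adults, given for the aged, rosiglitazone, irradiated, fracture and Prrx1-Cre libraries in turn, were 443, 218, 458, 260 and 214 at 1.5-fold and 23, 18, 43, 16 and 12 at 3-fold. They were 204, 137, 276, 143 and 95 with a floor of 20 CPM and 47, 41, 83, 34 and 16 with 100. Against the first adult alone they were 274, 230, 285, 186 and 99, and against the second 544, 287, 560, 428 and 513. All stromal classes together gave 486 in fracture and 120 in Prrx1-Cre, and the osteo-primed class gave 184 in aged, 326 in irradiated and 96 in fracture. Without clusters 0 and 10 the counts were 102, 64, 134, 65 and 56, of which 74, 59, 108, 51 and 38 were shared. Without integration 46, 34, 71, 22 and 29 genes were shared, and the cause was not tested, though the second adult then gave 51 cells. Other scalings, doublets kept, thinned sums and sums without stress-led clusters stayed within 1.5 times of each count. Of 1273 comparisons of single named genes 949 stayed within their intervals and 324 moved.

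The CAR-like share in fracture was 11.1% without integration, 45.4% and 48.0% at resolutions 0.4 and 1.2, 48.1% with doublets kept, 51.2% with 200 genes and 20% mitochondrial UMIs allowed, and 30.1% without clusters 0 and 10, against 53.5% and 49.6% in the adults under that last rule. The fibroblast- or tenocyte-like share in fracture was 32.5% without integration, 26.9% at resolution 0.4 and 25.6% with doublets kept. The osteo-primed share in the irradiated library was 13.9% without integration and 2.93% at resolution 1.2. The chondrocyte-like share in Prrx1-Cre was 2.44% at resolution 0.4. The cause of these moves was not tested. Of 292 comparisons of class shares 181 stayed within their intervals. Depth limits the irradiated library, where 1 UMI is a larger share of 1242075 than in the others and a count of 0 allows 2.42 CPM.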

Other observations

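The comparisons of osteo-primed cells and of shared genes and the tests of free RNA, endothelial carry-over, mural cells and splits were chosen after the results were seen, and the test of cartilage cells inside the CAR class before. Osteo-primed cells, which express Wif1, Limch1 and Alpl and were compared by the same rule as CAR-like cells, also differed from both adults in each condition. In fracture the repair gene Cthrc1 stood at 135 CPM against 10.4 and 4.39 (13.0-fold), the fibrillar collagen Col3a1 at 1132 against 92.1 and 132 (8.60-fold), the proteoglycan Aspn at 175 against 3.82 and 36.2 (4.82-fold) and Col1a1 at 3560 against 1159 and 959 (3.07-fold), while C3 was at 0.134 of the nearer adult. Such rises were not particular to fracture: in the Prrx1-Cre library Aspn was 6.98-fold, Col3a1 6.15-fold and Cthrc1 5.67-fold above the nearer adult. With rosiglitazone Fabp4 stood at 429 CPM against 12.0 and 13.2 (32.6-fold) and Lpl at 7384 against 1604 and 1611 (4.58-fold). In aged cells Snhg11 stood at 138 CPM against 4.36 and 2.20 (31.7-fold) and Efemp1 was 6.63-fold higher, while Wnt4 was at 0.231. This class joins clusters 4 and 7. Cluster 7, whose second-best marker list was osteoblast, held 23.3% and 21.2% of it in the adults, 14.2% in the aged, 6.64% in the rosiglitazone, 25% in the irradiated, 36.2% in the fracture and 39.1% in the Prrx1-Cre library, so that class levels also follow the mix. In Prrx1-Cre cells Col3a1 was at 1724 CPM in cluster 7 against 152.5 and 382 in the adults, but at 90.2 in cluster 4 against 70.8 and 50.8. Cthrc1 was at 119 against 18.8 and 18.0 in cluster 7, and at 11.4 against 7.38 and 0 in cluster 4. Aspn was at 564 against 14.6 and 144, and at 8.07 against 0 and 1.45. Fabp4 and Lpl with rosiglitazone, Snhg11, Efemp1 and Wnt4 in aged cells, and Cthrc1, Col3a1, Aspn and Col1a1 in fracture lay on the same side of both adults in each cluster, Snhg11 in cluster 7 by 1 UMI. In cluster 4 C3 in fracture stood at 9.41 CPM against 99.6 and 164, but in cluster 7 it lay between the adults. Col1a1 in cluster 4 of the fracture library stood at 856 CPM, the level in the 11 erythroid cells of that library (856). The adults differed at 413 genes in this class, and 184 genes were beyond both in the aged, 87 in the rosiglitazone, 326 in the irradiated (52 cells), 96 in the fracture and 55 in the Prrx1-Cre library, of which 48, 37, 69, 34 and 19 were also beyond in the CAR class.

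Rosiglitazone and irradiation shared 13 of their 42 and 82 higher genes in CAR-like cells, among them Cd36, Fabp4, Fabp5, Car3, Aqp7 and Bmp4, against 0.87 for independent lists and a mean of 0.11 (highest 2) in 100 simulated sets with no effect. Aged and rosiglitazone cells shared 15 lower genes, among them Bglap, Col1a1, Tnc and 4 haemoglobin genes (0.322 and 0.15), and irradiated and fracture cells shared 15 lower genes, among them C3, Ibsp, Rbpj and 4 haemoglobin genes (0.482 and 0.17). Only 2 adult libraries exist, so a split of the controls would leave 1 for each comparison, and part of the excess may come from the shared controls. The simulated libraries were also more alike than the real ones. Under the same rule 6 to 21 unchanged genes were called in simulated counts, while the first adult gave 22 to 87 and the second 140 to 260. The simulated means are therefore too low a yardstick, and the excess over them does not show a shared effect. Without integration Cd36 stood at 1.32 and 0.909 times the higher adult with rosiglitazone and irradiation, but few cells of the second adult were then in the class.

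Cartilage genes stood above both adults in Prrx1-Cre CAR-like cells. A few cartilage cells or doublets inside the class are argued against: the 5% of cells with most chondrocyte-marker UMIs (129 of 2564) held 16.6% of 3963 such UMIs, against 17% if they were spread evenly, and 74.5% of cells had at least 1. Free RNA from chondrocytes stays open and had the values it needs, since CAR-like cells held 0.593 times (0.523–0.674) the marker UMIs per cell of erythroid and neutrophil cells, or 1.6 times (1.41–1.82) by CPM.

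Bglap lay below both adults in aged and rosiglitazone CAR-like cells, at 4.50 and 12.6 CPM against 346 and 68.4. In the first adult CAR-like cells held 0.67 times (0.502–0.914) the Bglap UMIs per cell of mural, erythroid and neutrophil cells, or 1.17 times (0.877–1.6) by CPM, so free RNA from osteoblasts may set the level of the adults. The same stays open for Col1a1, which was at 427 CPM in CAR-like and 515 CPM in mural-like cells of the first adult, and for the matrix genes above both adults in fracture, since Col1a1 was at 903 and 856 CPM in its CAR-like and erythroid cells. Osteoblast-like cells were 2.08% and 1.12% of the adult libraries and 0.0902% and 0.121% of the aged and rosiglitazone libraries. Age and treatment stay open as untested explanations. Among osteo-primed cells Bglap was at 60.1 and 20.1 CPM in cluster 4 of the aged and rosiglitazone libraries against 375 and 136 in the adults, but at 2638 and 1692 in cluster 7 (30 and 20 cells) against 1122 and 2195, which is not below both.

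Mural genes and Emcn were higher in co-culture. Endothelial cells carried into the harvested RNA cannot be told apart from a change in BMSCs: over 9 pairs of libraries the summed rise of 7 low-baseline endothelial markers was at most 15.9 and at least −12.1 (SD 9.31), while Emcn rose by 17.5 to 27.1, and these markers were chosen after Emcn was seen. Mural cells among the cultured cells cannot be told apart from induction either, since 5 of 9 measured mural markers passed, all 9 were higher, and no table counts the cells. The real split of the 6 libraries gave 494 genes and the highest other split 11, with 1 of 10 splits giving as many, which are too few splits for a share under 0.05.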
